A study of Rattus norvegicus with 24 samples.

How the data were processed

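RNA was sequenced from 24 rat brain samples, 8 named normal control, 8 vehicle and 8 SKF, after poly(A) selection with a directional library kit, per the labels. The authors deposited a table of read counts per gene, aligned to build mRatBN7.2 per the labels, whose values are whole numbers. The authors also deposited a table of TPM (transcripts scaled to the same total in each library) for the same genes and samples, in which each column sums to 1e+06. The aligner and the counting program are not given in the sources used here. The count table was the input of every main test and the TPM table of an alternative. It holds 29539 genes, of which 6451 have an Ensembl identifier alone (0 could be matched to a symbol) and 2397 are numbered copies of a symbol, 179 of them tested.

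Groups were read from the sample titles. Replicate numbers recur across groups but do not pair samples in the labels, so samples were treated as unpaired. Total counts per library ran from 8911339 to 12383368. At this depth the biological coefficient of variation was 16.2%. Cldn5 was not analysed here, and Drd5 was under the filter.

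Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr by group, robust dispersion, quasi-likelihood F test) on all 24 libraries in 1 fit with 21 residual degrees of freedom. Adjusted p is Benjamini-Hochberg over the 14421 genes tested, with a threshold of 0.05, and each adjusted p of a gene is from edgeR unless another tool is named. Where a group had 0 counts, the fold is a lower bound against a floor of 3 counts per library. Before the data were examined, 37 gene lists of 644 genes were fixed from general knowledge, together with the tests, the alternatives and the rule for naming genes. Of those genes 592 are in the table and 533 were tested, 9 of them in more than 1 list. A list needed 3 tested members, which left 36 lists, since the list of sex-linked genes had 2. A list score is the mean log2 CPM (prior count 2) of its tested members in a library. Scores were compared by a two-sided exact permutation test over all 12870 assignments, whose smallest possible p is 0.0001554, and adjusted over the 36 lists of a comparison. Camera (preset correlation 0.01, or estimated) and fry from limma 3.58.1 were the other list tests, and "with an estimated correlation" refers to camera. Library measures (total counts, mitochondrial share, genes detected, share of the top 10 genes) were compared by the same permutation test.

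Genes were named by rule: with a mean log2 CPM of at least 1 and a symbol that is no placeholder, the 5 largest rises and 5 largest falls among those that passed, or the 5 smallest p in each direction where none did. To these were added the 2 members with the smallest adjusted p in each of up to 8 lists that passed with the largest differences, and a fixed set (Drd1, Drd5, Drd2, Gfap, Aif1, Ptprc, Cd68, Il1b, Tnf, Il6, Ccl2, Rbfox3, Mbp, Cldn5). A gene that the rule names in SKF against vehicle is not reported here. Other list members in the report were chosen after their values were seen, most for their small p and some because they moved against their list.

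The alternatives were DESeq2 1.42.0, RLE size factors, no filter (18951 genes), a filter of CPM 1 in 8 libraries (14342 genes), only the 2 groups compared, limma voom with sample weights, 1 surrogate variable (sva 3.50.0), the replicate number as a block, and limma on log2 TPM (pseudocounts 1 and 0.1, TPM of at least 0.5 in 8 libraries, 15280 genes). Each library was also left out in turn. The relation between the wound and agonist contrasts was compared with simulations and with all 70 splits of the vehicle libraries into 4 and 4. Other tools were Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9. The gene test was tested on simulated data with 50 genes changed at each size: in SKF against vehicle it called 72% at 1.5-fold, 88% at 2-fold and 96% at 4-fold, with 0 in the wrong direction and 7 unchanged genes called. The list test, tested on simulated data in 20 runs, called 26.7% of lists lowered by 0.25 (log2), 76.7% at 0.5 and 100% at 1, and of 660 other lists 6, 0 and 11.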

Results

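Gene expression was measured by RNA sequencing of poly(A)-selected RNA from 24 rat (Rattus norvegicus) brain samples in 3 groups of 8, named normal control, vehicle and SKF. SKF-81297 is an agonist of D1-like dopamine receptors, the family of Drd1 and Drd5. The series description places it in a stab wound model of the forebrain, with an injection into the peritoneum on each of 3 days and the first dose 1 h after the wound. The labels name the vehicle group by that word alone, and it is read here as wounded brain given the carrier. The brain region and the time of collection are not given. Total counts per library ran from 8911339 to 12383368, and 14421 of 29539 genes passed the filter on low counts. The labels do not say that the 8 samples of a group are 8 animals, so each p value measures spread between samples.

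The first principal component held 54.3% of the variance and parted every normal control library from every vehicle and SKF library. Its mean was -59.0 ± 4.83 (SD, n = 8) in normal control, 32.8 ± 9.56 in vehicle and 26.2 ± 4.72 in SKF. The difference of -6.59 between SKF and vehicle did not pass an exact two-sided permutation test (p = 0.105). On the second component, with 7.19% of the variance, normal control 6 stood at -61.0, away from the other 23 libraries. The share of counts from mitochondrial genes was 9.69% ± 1.10 (SD, n = 8) in normal control, 8.07% ± 0.660 in vehicle and 8.27% ± 0.811 in SKF, lower in vehicle by an exact permutation test (difference -1.62, adjusted p = 0.0118 over 12 tests of library measures) and in SKF (-1.42, adjusted p = 0.0214). The share of the top 10 genes was 10.5% in normal control, 8.45% in vehicle and 8.54% in SKF (exact permutation adjusted p = 0.00653 for each against normal control). More genes were detected in vehicle and SKF than in normal control (exact permutation adjusted p = 0.0214 and 0.0121).

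**Figure D1:**
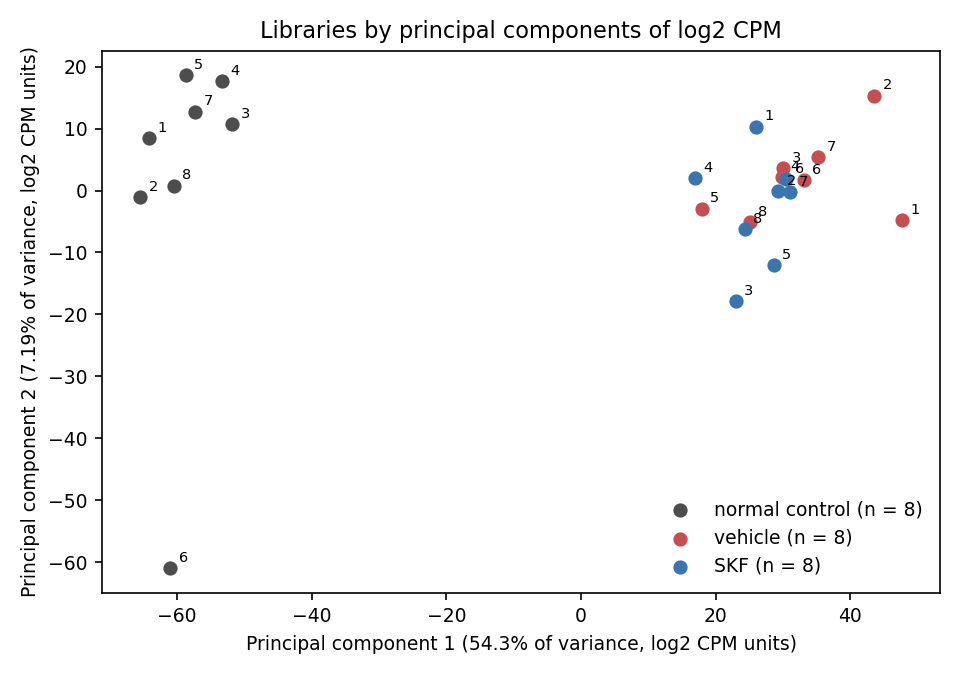
Each point is 1 library on the first and second principal components of log2 CPM, coloured by group and numbered by replicate. Normal control libraries lie at the left and vehicle and SKF libraries together at the right, with normal control 6 at -61.0 on the second component.

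Vehicle was set against normal control to ask how wounded brain differed from normal brain. The labels do not call normal control sham-operated. This contrast thus does not part the wound from surgery, the carrier or the piece of brain taken. Changes named after the wound below mean this whole contrast. Genes of inflammatory cytokines and chemokines rose, among them Ccl2 and Ccl7, which draw monocytes into tissue. Markers of neutrophils, of blood-derived macrophages and of reactive astrocytes, the glia that border a lesion, rose as well. The lists of myelin, of resting astrocytes and of transmitter receptors fell by the exact permutation test (adjusted p = 0.150, 0.120 and 0.170 with an estimated correlation).

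Ccl2 was higher by 9.06 ± 0.39 (log2 fold change ± SE, n = 8 per group) and Ccl7 by 8.43 ± 0.39. Cxcl3 and Cxcl2, ligands of the neutrophil receptor Cxcr2, had no counts in normal control and were at least 117-fold and at least 116-fold higher in vehicle, against a floor of 3 counts per library. Without vehicle 1 the bound for Cxcl2 was 57.1-fold. The edgeR test called 7783 genes, 3879 higher and 3904 lower, of which 1109 rose and 475 fell at least 2-fold. Of 36 gene lists, 33 passed the exact permutation test of their score, 22 higher and 11 lower in vehicle. With an estimated correlation camera, which sets a list against all other genes, called 9 lists, each of them higher in vehicle. The permutation test sets a list against no change. With 7783 of 14421 genes called, a list can pass it with no greater share of members called than among all genes. Exact permutation adjusted p was 0.000414 for homeostatic microglia, general neurons, oligodendrocyte precursors and glucocorticoid response, 0.00120 for pericytes, 0.00289 for B cells, 0.0101 for growth factors, 0.0108 for cortical neurons, 0.0248 for dopamine signalling and 0.0419 for cholesterol synthesis. The other lists that passed had 0.000243, from the smallest p the permutation test can give (0.0001554). In each list that passed, 8 of 8 vehicle libraries lay on the same side of the normal control median, except 7 of 8 for B cells, growth factors and cortical neurons and 6 of 8 for cholesterol synthesis. On the TPM scale, whose median gene stood 0.11 higher in vehicle (log2), 5476 genes were higher and 2408 lower.

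Among signals of inflammation, the list of pro-inflammatory cytokines and chemokines rose by 3.64 ± 0.21 (difference in list score, log2, ± SE), with 19 of 21 measured members higher and 2 not passing. Its members had a median change of 4.45. Il1b, an early interleukin of innate immunity, rose by 6.04 ± 0.90, and by 4.70 without vehicle 1, the library with most Il1b. Il6 rose by 4.89 ± 0.53, and by 5.99 without normal control 2. Tnf rose by 2.69 ± 0.25. Il11, an interleukin of the Il6 family, was at least 24.3-fold higher, with no counts in normal control. The fitted log2 fold change of Cxcl2, which leans on the small prior count where a group has none, was 11.49, and 10.47 without vehicle 1. The list of alternative activation and immune restraint rose by 1.98 ± 0.11, with 12 of 13 members higher. Socs3, a feedback inhibitor of cytokine signalling, rose by 6.06 ± 0.23 and the crosslinking enzyme Tgm2 by 2.06 ± 0.12. The list of NF-kB target genes rose by 1.17 ± 0.10 (adjusted p = 0.0680 with an estimated correlation), with 12 of 16 members higher. Vcam1, a leukocyte adhesion molecule, was the NF-kB target that fell, by 0.50. The list of complement genes rose by 1.38 ± 0.09, with 15 of 16 members higher, among them Itgam at 2.65 and C1r at 1.59. The interferon response list rose by 0.73 ± 0.08 (adjusted p = 0.150 with an estimated correlation), with 21 of 35 members higher and 3 lower. Ifitm3 was higher by 2.24 and Gbp2 by 2.09, while Mx2 was lower, with a log2 fold change of -0.46.

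The neutrophil list rose by 3.17 ± 0.14, with 8 of 9 members higher. S100a9, a calcium-binding protein abundant in neutrophils, rose by 5.75 ± 0.31 and the chemokine receptor Cxcr2 by 6.24 ± 0.37. Prtn3, a protease of neutrophil granules, was the member that fell, by 0.68. The list of blood-derived or border monocytes and macrophages rose by 3.13 ± 0.10 with all 13 members higher. The scavenger receptor Msr1 rose by 8.56 ± 0.26 and the endotoxin co-receptor Cd14 by 4.85 ± 0.20. Mcemp1, a membrane protein of mast cells and monocytes, was at least 40.3-fold higher, with no counts in normal control. The list of NADPH oxidase and Fc receptors rose by 2.34 ± 0.09 with all 12 members higher, Ncf4 by 4.01 ± 0.20 and Fcgr2b by 3.46 ± 0.16. Ptprc, the pan-leukocyte antigen CD45, rose by 2.37 ± 0.15. The list of T and NK cells rose by 0.87 ± 0.08 (adjusted p = 0.150 with an estimated correlation) with 4 of 8 members higher, Cd2 by 3.19 and Cd8a by 2.92. The list of B cells and plasma cells rose by 0.54 ± 0.15 (adjusted p = 0.545 with an estimated correlation), with Ighm the 1 of 3 members that passed, at 1.17. The red blood cell list rose by 1.88 ± 0.18 (adjusted p = 0.134 with an estimated correlation), with 4 of 5 members higher, among them Hba-a2 at 2.74.

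The disease-associated list of microglia and macrophages rose by 2.45 ± 0.09, with 16 of 20 members higher. Gpnmb, a glycoprotein of lipid-laden phagocytes, rose by 4.75 ± 0.13, the lectin Lgals3 by 5.63 ± 0.18 and the lysosomal protein Cd68 by 3.40 ± 0.21. Apoe, Lpl and Igf1 fell, by 0.88, 0.69 and 0.69. Of these 3, Apoe and Lpl act in lipid transport and Igf1 is a growth factor. The homeostatic microglia list had a difference of -0.53 ± 0.10 (adjusted p = 0.495 with an estimated correlation), with 4 of 11 members lower: Selplg, P2ry13, P2ry12 and Tmem119. P2ry12, a purine receptor of resting microglia, fell by 1.49. Csf1r, the receptor for macrophage growth, rose by 0.39. Aif1, the microglial marker Iba1, rose by 0.57 ± 0.17. Genes of MHC class II, which present antigen to helper T cells, rose by 1.86 ± 0.23 as a list (adjusted p = 0.120 with an estimated correlation), with 8 of 10 members higher, Cd74 by 2.21. The MHC class I list rose by 0.80 ± 0.11 (adjusted p = 0.150 with an estimated correlation), with 12 of 14 members higher and RT1-T24-4 and RT1-S3 lower.

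The reactive astrocyte list rose by 3.13 ± 0.12, with 18 of 19 members higher. Gfap, the astrocyte intermediate filament, rose by 2.46 ± 0.12, the protease inhibitor Timp1 by 5.94 ± 0.20 and the oncostatin M receptor Osmr by 3.23 ± 0.13. The homeostatic astrocyte list had a difference of -0.71 ± 0.08 (adjusted p = 0.120 with an estimated correlation), with 15 of 16 members lower. The glutamate transporter Slc1a2 fell by 1.00, while Glul, glutamine synthetase, rose by 0.52. The cell cycle list rose by 1.98 ± 0.10, with 24 of 27 members higher, among them Rrm2 at 3.05 ± 0.13 and the replication factor Mcm5 at 4.23 ± 0.18. The list of fibroblasts and extracellular matrix scar rose by 1.44 ± 0.11 (adjusted p = 0.0680 with an estimated correlation), with 20 of 28 members higher. Fn1, fibronectin, rose by 2.80, and Sparc and Col5a2 fell. The list of oxidative stress and iron handling rose by 0.74 ± 0.05 (adjusted p = 0.138 with an estimated correlation), with 8 of 13 members higher. Hmox1, the haem-degrading enzyme, rose by 5.95. The cell stress list rose by 0.70 ± 0.07 (adjusted p = 0.150 with an estimated correlation), with 12 of 15 members higher, Atf3 by 4.43. The glucocorticoid response list rose by 0.50 ± 0.09 (adjusted p = 0.545 with an estimated correlation), with 5 of 11 members higher and 3 lower, and metallothionein Mt2A rose by 3.24.

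The myelin list had a difference of -0.89 ± 0.10 (adjusted p = 0.150 with an estimated correlation), with 13 of 15 members lower, among them Mal at -1.57. Mbp, myelin basic protein, fell by 0.69 ± 0.12. The oligodendrocyte precursor list had a difference of -0.43 ± 0.08 (adjusted p = 0.284 with an estimated correlation), with 7 of 11 members lower, Gpr17 at -1.54 and the proteoglycan Vcan higher by 0.99. The list of glutamate and GABA receptors had a difference of -0.60 ± 0.10 (adjusted p = 0.170 with an estimated correlation), with 17 of 18 members lower, Grm3 at -1.05. The immediate early list, genes switched on by neuronal activity or by cAMP and CREB, had a difference of -0.69 ± 0.09 (adjusted p = 0.233 with an estimated correlation). Of its 19 members 10 were lower, among them Egr4 at -2.55 and Arc at -2.24, and 4 were higher, among them Ier2 at 1.48. The GABAergic interneuron list had a difference of -0.43 ± 0.05 (adjusted p = 0.150 with an estimated correlation), with 6 of 11 members lower. The general neuron list had a difference of -0.32 ± 0.07 (adjusted p = 0.248 with an estimated correlation), with 13 of 20 members lower. A score of 12 thalamus markers, defined after single genes were seen, had a difference of -1.78 ± 0.45, and the 9 of them not seen beforehand -1.38 ± 0.34. These 9 mark the same tissue in the same libraries, so they are no independent test. Rbfox3, the nuclear antigen NeuN, did not pass (0.06 ± 0.10, edgeR adjusted p = 0.598).

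Smaller or less steady list differences followed. The list of cortical projection neurons had a difference of -0.35 ± 0.12 (adjusted p = 0.588 with an estimated correlation), with 7 of 14 members lower, Neurod6 at -1.99, and 2 higher. On the TPM scale its difference was -0.21 (adjusted p = 0.115 by the exact permutation test). In the replicate block its exact adjusted p was 0.0703. The dopamine signalling list had a difference of -0.46 ± 0.19 (adjusted p = 0.495 with an estimated correlation), with 5 of 13 members lower, and Ddc, which makes dopamine from its precursor, fell by 2.26. That call was lost in the exact permutation test without normal control 6 (-0.32, adjusted p = 0.0510), without vehicle 4 (-0.38, adjusted p = 0.0549) and on the TPM scale (-0.29, adjusted p = 0.115). The cholesterol synthesis list had a difference of -0.14 ± 0.06 (adjusted p = 0.545 with an estimated correlation), with 7 of 16 members lower. Its exact permutation adjusted p of 0.0419 rose to between 0.0520 and 0.0787 without vehicle 3, 5, 7 or 8 or without normal control 1, 2, 3, 5, 7 or 8, and to 0.851 on the TPM scale. In the replicate block its exact adjusted p was 0.128. The list of growth and trophic factors rose by 0.28 ± 0.09 (adjusted p = 0.523 with an estimated correlation), with 7 of 17 members higher and 4 lower. Hbegf rose by 2.32 and Bdnf fell by 1.81. The list of pericytes and smooth muscle rose by 0.53 ± 0.10 (adjusted p = 0.678 with an estimated correlation), with 5 of 12 members higher and 4 lower.

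The lists of endothelium (0.09, exact permutation adjusted p = 0.131), striatal projection neurons (-0.59, adjusted p = 0.186) and choroid plexus (0.22, adjusted p = 0.710) did not pass. For endothelium and choroid plexus the members' medians were -0.09 and -0.05, opposite in sign to the scores. By the exact permutation test, the endothelial list passed on the TPM scale (0.21, adjusted p = 0.00228) and without normal control 4 and 6 together (0.14, adjusted p = 0.0312). The striatal list passed without normal control 1 (-0.81, exact permutation adjusted p = 0.0205), but its difference was -0.29 without normal control 6. The choroid plexus score turned to -0.16 without normal control 6 and reached 0.42 without normal control 3, and the endothelial score was 0.06 without vehicle 8. Over these lists, the number of members past the threshold adjusted over the list alone was the same as over all genes for 28 lists. It was 20 for cytokines, 14 for NF-kB targets, 25 for interferon, 23 for matrix scar, 15 for immediate early genes, 11 for pericytes, 5 for striatal neurons and 2 for choroid plexus.

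Drd1, the main receptor of the agonist, had a log2 fold change of -0.92 ± 0.49 (edgeR adjusted p = 0.119), and -0.09 without normal control 6. Drd2 had -1.03 ± 0.55 (edgeR adjusted p = 0.117), and -0.16 without normal control 6, but passed without normal control 1 (-1.21, adjusted p = 0.0429). Drd5 was under the filter, with mean counts of 7.13 ± 1.64 (SD, n = 8) in normal control, 4.38 ± 2.26 in vehicle and 5.50 ± 2.07 in SKF. Gbx2 and Shox2, transcription factors of the thalamus, fell by 3.76 ± 0.65 and 3.73 ± 0.80, although limma voom with sample weights gave Shox2 an adjusted p of 0.0523. The muscle genes Myh4, Tnnt3 and Acta1 had the largest fitted falls, -5.79, -4.21 and -4.10, which rested on normal control 4. Without that library edgeR gave -0.78 for Myh4 (adjusted p = 0.00873), 1.75 for Tnnt3 (adjusted p = 0.000503) and -0.20 for Acta1 (adjusted p = 0.409). Normal control 6 differs from the other 23 libraries in the Y-linked Eif2s3y (0 counts against 538 to 833) and in Ddx3 (1 against 497 to 779), as well as in Drd1 and Drd2. The labels give neither sex nor region, and the source of the muscle transcripts in normal control 4 is not given. Without normal control 4 and 6 together the edgeR test called 7669 genes, 3892 higher and 3777 lower.

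**Figure D2:**
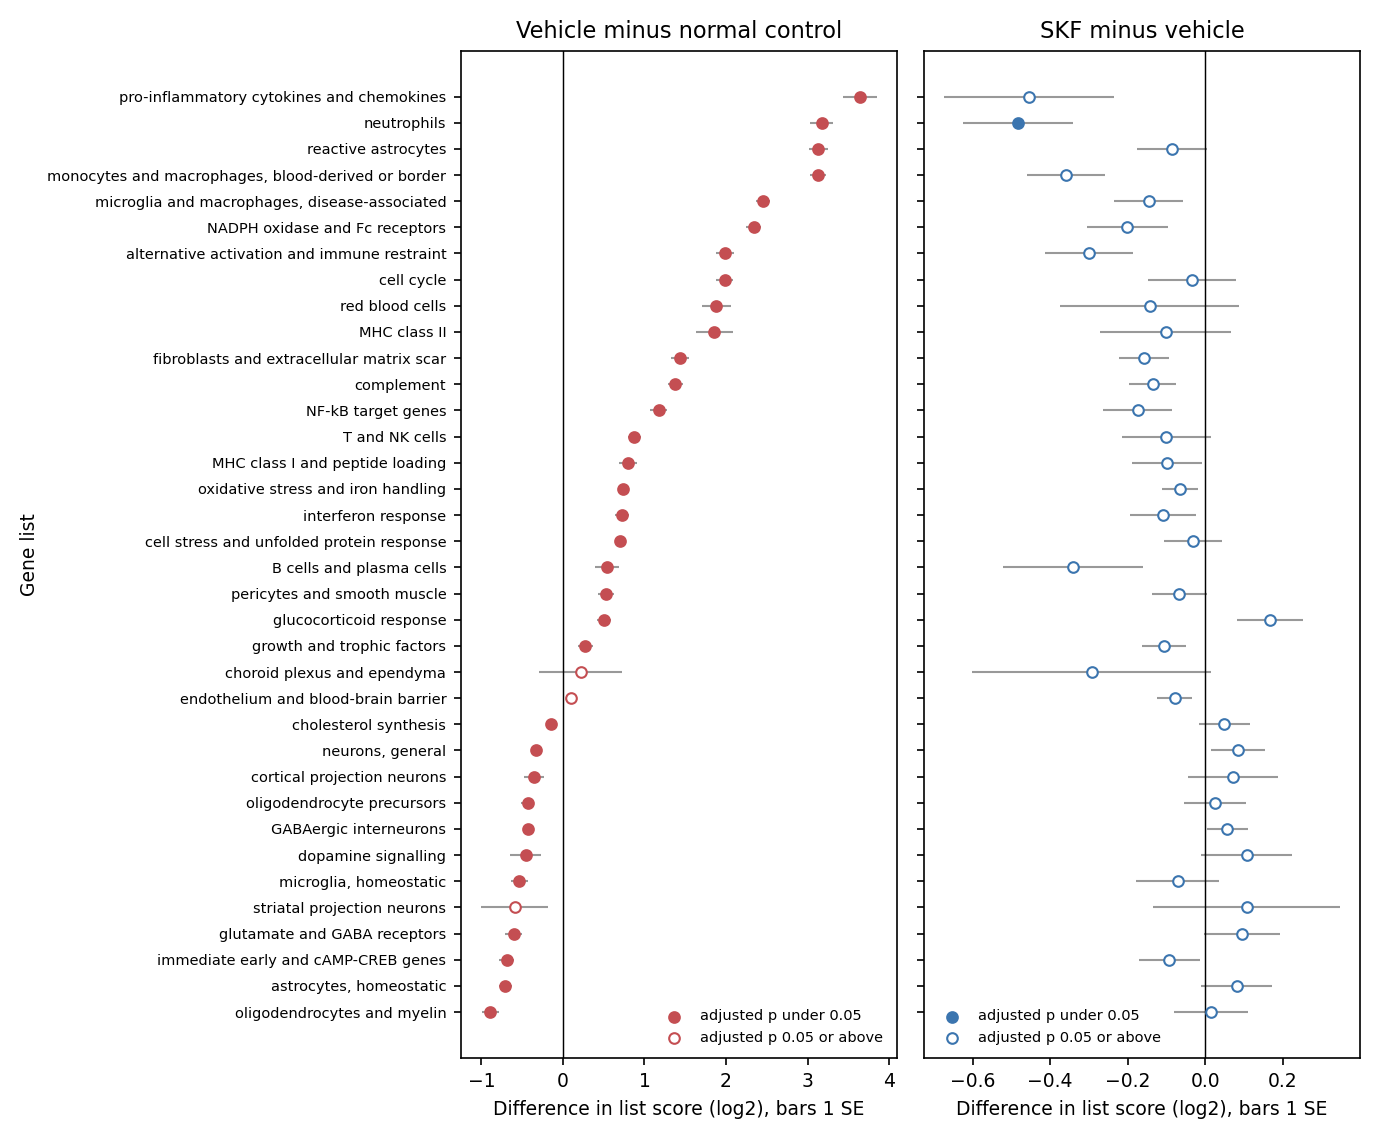
Points give the difference in score of each of 36 gene lists (log2, bars 1 SE), for vehicle minus normal control at the left and SKF minus vehicle at the right, on separate axes, filled where the adjusted p was under 0.05. At the left 33 lists passed, from 3.64 for cytokines to -0.89 for myelin, and at the right the neutrophil list passed, at -0.48.

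SKF was set against vehicle to ask what the agonist changed in wounded brain. Markers of neutrophils, the first blood cells to enter a wound, were lower in SKF as a group. No single gene passed, and no list of astrocytes, neurons or myelin did. Markers of blood-derived macrophages and inflammatory cytokines leaned the same way as neutrophils without passing.

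The neutrophil list score had a difference of -0.48 ± 0.14 (log2, ± SE, n = 8 per group), all 8 SKF libraries lay below the vehicle median and 7 lay below every vehicle library. Of the 16 genes on this list, 7 were under the filter on low counts. All 9 measured members had negative changes, among them S100a9 at -0.93 ± 0.20, Cxcr2 at -0.84 ± 0.22 and S100a8 at -0.68. Csf3r, the receptor for the granulocyte growth factor, had -0.50. Gfap (0.08 ± 0.11), Ptprc (-0.21 ± 0.14) and Rbfox3 (0.09 ± 0.10) did not pass. The neutrophil list was the 1 of 36 lists that passed (exact permutation p = 0.000932, adjusted p = 0.0336). With an estimated correlation its camera adjusted p was 0.0355, and its fry adjusted p was 0.0405. Of its members, 4 passed adjusted over the list alone (S100a9, Cxcr2, Csf3r and S100a8) and 0 over all genes. The call was a narrow one: the exact permutation adjusted p was 0.0503 to 0.112 without SKF 2, 3, 4, 5, 6, 7 or 8 or without vehicle 1, 2, 3, 6 or 7, with differences from -0.38 (without vehicle 1) to -0.50.

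The edgeR test called 0 of 14421 genes, with 715 at an unadjusted p under 0.05 and a smallest adjusted p of 0.485. DESeq2 also called 0, with 840 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0603, and limma voom with sample weights called 0, with 875. In tests on simulated data with these libraries, 72% of genes changed 1.5-fold and 88% of genes changed 2-fold were called, and fewer at smaller changes. Many genes were changed at once in those data, which makes the adjusted threshold easier to pass. The rates can be lower where few genes change, so they do not show what the 0 calls could have missed. The lowest p values among lower genes belonged to Tec, a kinase of haematopoietic cells, at -0.39 ± 0.08, to S100a9, to Crybg2 at -0.43 ± 0.10, to Fcgr2a_2, a numbered copy whose locus is uncertain, at -0.76 ± 0.18, and to Csf2rb at -0.38 ± 0.10. Among higher genes those with the lowest p included Tmem114 at 1.09 ± 0.25, Dkk3, a relative of secreted Wnt inhibitors, at 0.30 ± 0.08, the stress-induced Ddit4 at 0.31 ± 0.09 and Tshz2 at 0.44 ± 0.13. Adjusted p ran from 0.485 for Tec to 0.704 for Tshz2.

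Other groups of immune genes had negative differences that did not pass. The list of blood-derived or border monocytes and macrophages had a difference of -0.36 ± 0.10 (exact permutation adjusted p = 0.0867), with 12 of 13 members negative. It passed without SKF 1 (-0.42, adjusted p = 0.0112) and without vehicle 5 (-0.40, adjusted p = 0.0420), and by camera with an estimated correlation (adjusted p = 0.0355) and fry (adjusted p = 0.0452). The list of alternative activation and immune restraint had -0.30 ± 0.11 (adjusted p = 0.235 by permutation, 0.0355 by camera with an estimated correlation and 0.0452 by fry), all 13 members negative. Of these, 5 passed adjusted over the list alone and 0 over all genes. The cytokine list had -0.46 ± 0.22 (permutation adjusted p = 0.268), with 20 of 21 members negative, 3 passing adjusted over the list alone and 0 over all genes. Il1b had -1.92 ± 0.61 (edgeR adjusted p = 0.838), and -0.57 without vehicle 1. Tnf had -0.54 ± 0.21, Il6 -0.58 ± 0.33, Ccl2 -0.24 ± 0.19 and Cd68 -0.30 ± 0.17, with adjusted p of 0.889, 0.937, 0.960 and 0.937. Complement and NF-kB targets had differences of -0.14 and -0.17, each with 2 members passing adjusted over the list alone and 0 over all genes, and the remaining 31 lists had the same count both ways. The glucocorticoid response list had the largest positive difference, 0.17 ± 0.09 (permutation adjusted p = 0.268).

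No list of the brain's own cells passed here. The choroid plexus list had a difference of -0.29 ± 0.31 (permutation adjusted p = 0.561), and -0.17 without SKF 3, -0.12 without SKF 5 and -0.16 without vehicle 2. The reactive astrocyte list had a difference of -0.09 ± 0.09 (permutation adjusted p = 0.561), the homeostatic astrocyte list 0.08 ± 0.09 and the general neuron list 0.08 ± 0.07. Aif1 had 0.17 ± 0.16 and Mbp -0.24 ± 0.12, with edgeR adjusted p of 0.968 and 0.937. The dopamine signalling list had a difference of 0.11 ± 0.12 (permutation adjusted p = 0.561). The immediate early list, which includes cAMP and CREB genes, had -0.09 ± 0.08 (permutation adjusted p = 0.554), with 14 of 19 members negative. Its difference was -0.04 without SKF 8 and -0.06 without vehicle 1. Without vehicle 2 the reactive astrocyte and neuron lists had -0.03 and 0.03, without vehicle 1 homeostatic astrocytes 0.03, and without vehicle 4 dopamine signalling 0.03. Without vehicle 5 reactive astrocytes had -0.13 and without vehicle 8 homeostatic astrocytes 0.12. The striatal list had 0.11 ± 0.24 (permutation adjusted p = 0.750), with a members' median of -0.01, and turned to -0.00259 without SKF 8 and -0.06 without vehicle 4, and was 0.22 without vehicle 8. Drd1 had 0.22 ± 0.49, and -0.00172 without SKF 8. Drd2 had 0.00457 ± 0.55, with a sign that turned without SKF 3 or 8 or vehicle 1, 4 or 6, down to -0.25 without SKF 8.

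**Figure D3:**
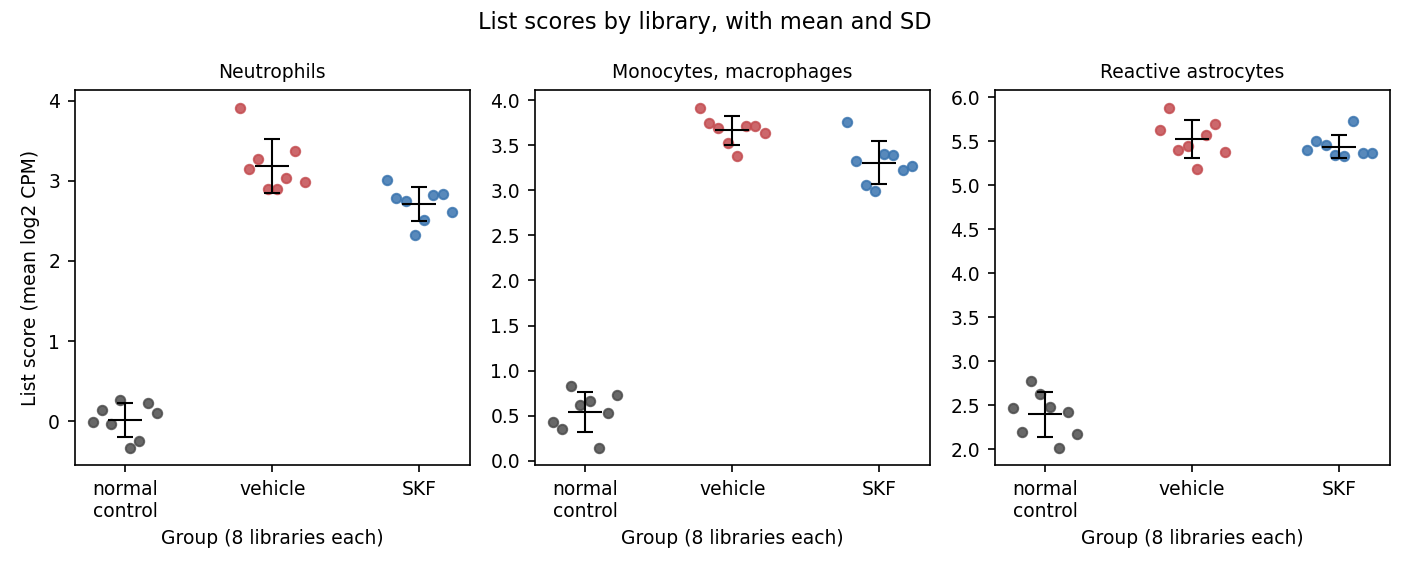
Each point is the list score (mean log2 CPM) of 1 library for neutrophils, monocytes and macrophages, and reactive astrocytes, with bars for the mean and SD of the 8 libraries of a group. Neutrophil scores averaged 0.01 in normal control, 3.19 in vehicle and 2.71 in SKF.

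The changes of the agonist were set beside those of the wound across genes. Across 14421 genes, which are not independent replicates, the log2 fold changes of SKF against vehicle and of vehicle against normal control had a Pearson r of -0.399 and a covariance of -0.0515. Both contrasts share the vehicle libraries, and simulations with a wound effect alone gave a covariance of -0.0148. With the vehicle libraries split 4 and 4 between the contrasts, the covariance averaged -0.0377 over 70 splits and was negative in 68, with a mean r of -0.237. The splits reuse the same vehicle libraries, so they are not independent of each other. When vehicle and SKF labels were exchanged in all 12870 ways, the exact p of the covariance was 0.0973. Of the 1109 genes that rose at least 2-fold in vehicle, 81.4% were lower in SKF than in vehicle, with a median change of -0.16, and of the 475 that fell 63.8% were higher. Those genes were picked with the vehicle libraries that the second contrast uses. With separate vehicle libraries the shares averaged 74.6% (53.95% to 88.2% over the splits) and 55.3% (28.5% to 81.3%).

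A score of 1038 genes raised by the wound, defined after the data were seen from the mean of vehicle and SKF against normal control, had a difference of -0.17 ± 0.07 between SKF and vehicle and lay below the vehicle median in 8 of 8 libraries. The exact permutation p was 0.0320, and 0.0640 adjusted over this score and that of 485 genes lowered by the wound, which differed by 0.01 ± 0.10 (p = 0.895 by the same exact test, with a sign that turned without vehicle 1 or 4 or SKF 1, 4 or 8). For the raised score, the exact p was 0.0614 without vehicle 1 (-0.14) and 0.0614 without vehicle 2 (-0.14). It was 0.0583 without vehicle 7 (-0.16), 0.0626 without SKF 3 (-0.15) and 0.0629 without SKF 4 (-0.15).

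SKF was set against normal control to ask how treated wounded brain differed from normal brain. Chemokines, neutrophil and macrophage markers and reactive astrocyte genes rose here too. The lists of myelin, which insulates axons, and of resting astrocytes fell by the exact permutation test (adjusted p = 0.157 and 0.136 with an estimated correlation). Dopamine signalling genes as a group did not pass.

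Ccl2 rose by 8.81 ± 0.40 (log2 fold change ± SE, n = 8 per group), Msr1 by 8.29 ± 0.26 and Gfap by 2.54 ± 0.12. Cxcl3, Cxcl2, Mcemp1 and Trem1, a receptor that amplifies myeloid activation, had no counts in normal control and were at least 55.2-fold, 34.9-fold, 26.9-fold and 15.3-fold higher, against the same floor. The neutrophil list rose by 2.69 ± 0.11, with S100a9 at 4.82 ± 0.31 and Cxcr2 at 5.40 ± 0.38. The edgeR test called 7239 genes, 3682 higher and 3557 lower, of which 972 rose and 482 fell at least 2-fold, and on the TPM scale 4996 were higher and 2296 lower. Of 36 lists, 29 passed the exact permutation test, 20 higher and 9 lower, with adjusted p from 0.000233 to 0.0226. With an estimated correlation camera called 9 lists, each of them higher in SKF, with adjusted p of 0.00548 to 0.0180. Here too a list can pass the permutation test with no greater share of members called than among all genes.

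The cytokine list rose by 3.18 ± 0.10, reactive astrocytes by 3.04 ± 0.10, blood-derived macrophages by 2.77 ± 0.11, disease-associated microglia by 2.31 ± 0.09, NADPH oxidase and Fc receptors by 2.14 ± 0.09 and cell cycle by 1.95 ± 0.10. MHC class II rose by 1.76 ± 0.24 (adjusted p = 0.124 with an estimated correlation). In these lists Ccl7 rose by 7.93, Timp1 by 5.80, Osmr by 3.04, Cd14 by 4.53, Gpnmb by 4.53, Lgals3 by 5.42, Fcgr2b by 3.25, Ncf4 by 3.67, Rrm2 by 2.95, Mcm5 by 4.04, RT1-DMb by 1.87 and RT1-DMa by 1.38. Il1b rose by 4.13 ± 0.96, Tnf by 2.14 ± 0.26, Cd68 by 3.10 ± 0.21, Ptprc by 2.16 ± 0.15 and Aif1 by 0.74 ± 0.17. Il6 rose by 4.30 ± 0.55, and by 5.40 without normal control 2. The myelin list had a difference of -0.88 ± 0.12 (adjusted p = 0.157 with an estimated correlation) and Mbp fell by 0.93 ± 0.12. The homeostatic astrocyte list had -0.62 ± 0.05 (adjusted p = 0.136 with an estimated correlation) and the immediate early list -0.78 ± 0.09 (adjusted p = 0.181 with an estimated correlation).

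The general neuron list had -0.24 ± 0.06 (adjusted p = 0.335 with an estimated correlation) and the cortical list -0.28 ± 0.10 (adjusted p = 0.729 with an estimated correlation). By the exact permutation test neither passed on the TPM scale (-0.14, adjusted p = 0.0576, and -0.17, adjusted p = 0.131). In the replicate block the exact adjusted p of the cortical list was 0.0776. Glutamate and GABA receptors had -0.51 ± 0.08 (adjusted p = 0.197 with an estimated correlation), homeostatic microglia -0.60 ± 0.09 (0.291), oligodendrocyte precursors -0.41 ± 0.07 (0.286) and GABAergic interneurons -0.38 ± 0.05 (0.191). NF-kB targets rose by 1.00 ± 0.06 (adjusted p = 0.122 with an estimated correlation), matrix scar by 1.28 ± 0.11 (0.111), red blood cells by 1.74 ± 0.18 (0.137), T and NK cells by 0.77 ± 0.12 (0.185) and glucocorticoid response by 0.67 ± 0.09 (0.291). MHC class I rose by 0.70 ± 0.10 (adjusted p = 0.181 with an estimated correlation), oxidative stress and iron by 0.68 ± 0.04 (0.169), cell stress by 0.67 ± 0.05 (0.157), interferon by 0.62 ± 0.10 (0.175) and pericytes by 0.46 ± 0.10 (0.874). Complement rose by 1.24 ± 0.08 and immune restraint by 1.69 ± 0.08.

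The lists that did not pass here were dopamine signalling (-0.35, exact permutation adjusted p = 0.0612), growth factors (0.17, adjusted p = 0.0612), cholesterol synthesis (-0.09, adjusted p = 0.0705), striatal neurons (-0.49, adjusted p = 0.262), B cells (0.20, adjusted p = 0.309), endothelium (0.01, adjusted p = 0.764) and choroid plexus (-0.08, adjusted p = 0.893). Without normal control 1, dopamine signalling (-0.45, exact permutation adjusted p = 0.00260) and striatal neurons (-0.71, adjusted p = 0.0134) passed, and dopamine signalling passed without SKF 8 (-0.41, adjusted p = 0.0260). Without normal control 6 the differences were -0.21 for dopamine signalling (exact permutation adjusted p = 0.117), -0.18 for striatal neurons (0.495), 0.11 for growth factors and -0.45 for choroid plexus, and for B cells 0.09 without SKF 6. Growth factors passed without SKF 4 (0.19, exact permutation adjusted p = 0.0455) or normal control 3, 5 or 7 (0.20, 0.20 and 0.19), and cholesterol synthesis without SKF 5 (-0.11, adjusted p = 0.0462) or normal control 6 (-0.12, adjusted p = 0.0102). On the TPM scale growth factors (0.20, exact permutation adjusted p = 0.00539) and endothelium (0.12, adjusted p = 0.0440) passed, and dopamine signalling passed with genes shared between lists left out (-0.39, adjusted p = 0.000224). The endothelial members had a median of -0.10, opposite in sign to the score, which turned to -0.00159 without SKF 1 and -0.00799 without normal control 2. The choroid plexus score was positive without SKF 3 or 5 or normal control 3, 4, 5 or 7, up to 0.13 without normal control 3. The count of members adjusted over the list alone equalled that over all genes for 29 lists.

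Among single genes, Rbfox3 (0.15 ± 0.10, edgeR adjusted p = 0.197), Drd1 (-0.70 ± 0.48, adjusted p = 0.241) and Drd2 (-1.03 ± 0.55, adjusted p = 0.124) did not pass. Rbfox3 passed on the TPM scale by limma (0.25, adjusted p = 0.0404). Drd1 and Drd2 had 0.12 and -0.16 without normal control 6, and Drd2 had -1.21 (edgeR adjusted p = 0.0467) without normal control 1. The largest fitted falls were the muscle genes Myh4 (-5.99), Tnnt3 (-4.95), Acta1 (-4.01), Mb (-3.67) and Myh2 (-3.56). Without normal control 4 edgeR gave -0.99 (adjusted p = 0.00156), 1.01 (adjusted p = 0.0443), -0.11 (0.676), -0.36 (0.524) and -0.00578 (0.986).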

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

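A value was singled out when the highest or lowest library of a group stood apart from the nearest by more than 0.526 of the group's range, Dixon's 95% limit for 8 libraries. Of 267 groups of values 23 did so, where chance alone would give about 1 in 20, or 13.35. Some of the genes checked, such as Myh4 and Acta1, were named for falls that rested on normal control 4. Their flags were thus partly fixed by the naming, and the excess over 13.35 cannot be read plainly. In normal control 4 the values (log2 CPM) were Acta1 9.68, Mb 7.23, Myh2 7.56, Myh4 9.41 and Tnnt3 7.45, and the pericyte list score was 4.60. In normal control 6 Shox2 was -2.43, the striatal list 7.89 and the disease-associated microglia list 2.81. Other normal control values were Aif1 3.36 in library 3, Il6 -0.82 in 2, T and NK cells -0.51 in 1, interferon response 2.60 in 5 and homeostatic astrocytes 7.92 in 2. In vehicle 1 the neutrophil list was 3.91 and Il1b 6.51, and in vehicle 2 Mbp was 12.96 and Rbfox3 6.94. In SKF 8 the striatal list was 6.05, the dopamine list 5.49 and Drd2 5.65. Reactive astrocytes were 5.73 in SKF 6 and endothelium 5.10 in SKF 1.

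For the patterns weighed here, some tests were chosen after the result was seen. They were those without vehicle 1, without vehicle 1 and 2, with split vehicle libraries and against the neuron score. The tests at equal list scores and the correlation with wound markers were chosen before their own results were seen. The patterns they address had been seen by then, and the wound-raised score and the thalamus list were defined after the data were seen.

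The neutrophil list was lower in SKF than in vehicle. Without vehicle 1, the vehicle library with the highest score, the difference was -0.378 (SE 0.103, exact p = 0.00202 before adjustment over lists and 0.0727 after). The negative difference thus did not rest on that library alone, but the call over all lists was lost without it. At equal red blood cell score the difference was -0.456 (SE 0.143, permutation p = 0.00280 before adjustment over lists). The red blood cell score itself did not differ clearly between SKF and vehicle (-0.14 ± 0.23). Adjusting for it therefore cannot exclude a difference in blood that the score does not follow. At equal reactive astrocyte score the difference was -0.422 (SE 0.136, permutation p = 0.00544 before adjustment over lists). That score itself differed little between SKF and vehicle (-0.09 ± 0.09). Adjusting for it therefore cannot exclude a smaller share of wounded tissue that the score does not follow. An effect of the agonist could underlie the lower neutrophil list, but fewer neutrophils and lower expression per cell were not separated here.

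The score of genes raised by the wound had a negative difference between SKF and vehicle that did not pass once adjusted (exact permutation adjusted p = 0.0640 over 2 scores). Sharing of the vehicle libraries between contrasts, together with spread between libraries, was not excluded. The covariance with split libraries averaged -0.0377, but the splits reuse the same vehicle libraries and ran from -0.0732 to 0.00460. Exchanging vehicle and SKF labels, which keeps the sharing, gave covariances from -0.0831 to 0.0470. The unsplit covariance was -0.0515, with an exact label-exchange p of 0.0973. At equal reactive astrocyte score, whose genes overlap those raised by the wound, the difference in score was -0.124 (SE 0.0535, permutation p = 0.0423). Without vehicle 1 and 2 the difference was -0.0990 (SE 0.0642, exact p = 0.134), so an effect of the agonist and the weight of these 2 libraries cannot be told apart.

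Thalamus markers were lower in vehicle than in normal control. The thalamus score fell further than the general neuron score, by a difference of -1.46 (SE 0.413), and of -1.06 (SE 0.301) for the 9 markers not seen to fall beforehand. These 9 mark the same tissue in the same libraries, and the list was written after thalamus genes were seen to fall. The gap is thus no independent test of a loss of neurons of every kind. If larger wounds took more thalamus, its score would fall as wound markers rise: across the 16 vehicle and SKF libraries, r with the reactive astrocyte score was -0.368 (permutation p = 0.160; Spearman -0.341, p = 0.195). It was -0.544 within vehicle, -0.105 within SKF and -0.386 without the 2 farthest libraries. Wound loss and a difference in the region dissected cannot be told apart.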

How the results depend on the processing

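Of the alternatives, 138 of the list results of vehicle against normal control stayed the same, 5 weakened and 1 strengthened. For SKF against vehicle 141 stayed the same, 2 reversed and 1 weakened, the neutrophil list in the replicate block. A list that did not pass counts as the same if its sign held and it still did not pass, so the 141 say little. For SKF against normal control 136 stayed the same, 2 reversed, 3 weakened and 3 strengthened. Of named genes, 342, 226 and 328 stayed the same in the 3 comparisons, and the weakened ones were mostly muscle genes. No named gene passed in SKF against vehicle, so the 226 mean that a sign held and no call was gained. On the TPM scale 2408 genes (pseudocount 1) and 2358 (0.1) were lower in vehicle and 2296 and 2252 in SKF against normal control; the cause was not tested. Camera with an estimated correlation called 9 lists in vehicle and 9 in SKF against normal control. In SKF against vehicle, lists called numbered 17 by camera with the preset correlation, 3 by camera with an estimated one, 3 by fry, 0 in the replicate block and 0 without vehicle 1 and 2. Leaving out 1 library gave 0 to 2. The neutrophil adjusted p by exact permutation was 0.0938 in the replicate block, 0.0112 to 0.112 leaving out 1 library and 0.168 without vehicle 1 and 2. The smallest p of the replicate block test is 0.00781, so no list can pass it unless 6 reach that p, and its 0 in SKF against vehicle does not show that the calls depend on the block. In it the cortical list lost its call in vehicle (exact adjusted p = 0.0703) and in SKF (0.0776) against normal control, and cholesterol synthesis in vehicle (0.128). Same-number samples had a mean correlation of -0.0482 (-0.241 to 0.0783), none the best match. The wound-raised score differed by -0.210 to -0.140 leaving out 1 library and by -0.0990 without vehicle 1 and 2. The split vehicle libraries gave an r of -0.237. Signs that turned were Tnnt3 in vehicle against normal control (DESeq2 1.60, voom 0.34, TPM with 0.1 0.57) and in SKF against normal control (DESeq2 0.85), and Drd2 in SKF against vehicle (RLE -0.00198, only 2 groups -0.000717, surrogate variable -0.218, replicate block -0.0340). On the TPM scale they were myelin -0.0110 and oligodendrocyte precursors -0.000917 in SKF against vehicle, and choroid plexus 0.00219 and cholesterol synthesis 0.0114 in SKF against normal control; the cause was not tested. Leaving out libraries in pairs, all list leave-outs and the wound-raised score were chosen after seeing the data.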

Other observations

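Markers of the thalamus, hypothalamus and skeletal muscle were scored after single genes of each had been seen, and the split counts below were also chosen after the result was seen. The thalamus score, of 12 genes such as Slc17a6 and Tcf7l2, differed by -1.78 ± 0.45 (log2, ± SE, n = 8 per group) in vehicle against normal control with 11 of 12 members lower. With the 9 members not seen beforehand it differed by -1.38 ± 0.34. In SKF against normal control the score of 12 differed by -1.50 ± 0.48. No p is printed for either contrast, as 3 markers were seen beforehand and the others mark the same tissue. In SKF against vehicle the score differed by 0.28 ± 0.31 (exact p = 0.370), with 0.11 without SKF 4. Of 10 tested markers of hypothalamus and habenula, edgeR called 4 lower and 1 higher in vehicle against normal control. It called 7 lower and 1 higher in SKF against normal control, and 0 in SKF against vehicle. Their score differed by -0.44, -0.70 and -0.26 in the same order (exact p = 0.414, 0.161 and 0.480). Leaving out 1 library, the first ran from -0.75 (normal control 6) to -0.21 (normal control 5), the second from -1.004 (exact p = 0.0235, normal control 6) to -0.46 (normal control 5), and the third ran from -0.47 (vehicle 5) to -0.09 (vehicle 2). The muscle score differed by -0.73, -0.81 and -0.09 (exact p = 0.795, 0.588 and 0.475), and without normal control 4 the first 2 turned to 0.11 and 0.02. The third ran from -0.15 without vehicle 2 to -0.03 without vehicle 1.

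Single libraries stood apart in gene counts, and the sex of the animals and the piece of brain taken are not in the labels. Normal control 6 had 0 counts of the Y-linked gene Eif2s3y (538 to 833 in the others), 1 of Ddx3 (497 to 779), 13 of Ttr, the choroid plexus thyroid hormone carrier (at least 3035), and 42 of Slc17a6. It had 2334 counts of Drd1 and 1857 of Drd2, where the highest of the other 23 libraries had 835 and 575. Normal control 4 had 8001 counts of Myh4, 9654 of Acta1, 3419 of Ckm and 2135 of Oxt, a hypothalamic hormone. Normal control 5 had 307 counts of Cga, a pituitary hormone subunit. Vehicle 1 had 892 counts of Il1b, 1763 of Nos2 and 1498 of Cxcl2, where the highest other library had 135, 410 and 317.

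The gene counts were set against other splits of the same 16 libraries. In vehicle against normal control 1 of 100 splits, the real one, gave as many as 7783 genes (highest other 5679). That other split kept 7 of the 8 libraries of a group together. In SKF against normal control 1 of 100 gave as many as 7239 (highest other 0). No other split drawn there kept more than 6 together, so the highest other counts of these comparisons cannot be set against each other. In SKF against vehicle all 100 of 100 gave at least the 0 genes called (highest other 2), as any split must, so that count tests nothing. There, 30 of 100 gave as many as 715 at an unadjusted p under 0.05 (highest other 1560).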
